A study of Mus musculus with 99 samples.

How the data were processed

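Total RNA was taken from flash-frozen mouse liver or liver tumour and made into Illumina TruSeq libraries, per the labels' protocols. The values were FPKM (fragments scaled by transcript length and by the mapped fragments of the library), computed by the authors and deposited as 1 table for the whole series with 24318 rows and 99 columns. The submitters' processing notes name Cuffdiff and the mouse genome build mm9, and the version, the aligner and the gene annotation are not given in the sources used here. FPKM values are relative to the total of each library and to transcript length, and how reads were shared between near-identical genes is not stated, so genes of the Mup, Cyp2c, Cyp4a12, Gstm, Orm, Serpina1, Lyz and Hamp families carry that uncertainty. No mm9 annotation was used here, so gene positions are not given, and genes carry the symbols of the table.

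Columns were matched to sample titles by genotype, age, set and replicate number, and 0 columns were left unmapped. In 12 columns the tumour word differed from the title, since the separate PKO set at 7 months is named HCA where the title says liver, and the tumours of PKO at 12 months HCA and of DKO at 7 and 12 months HCC where it says tumour. The tumour average so joins columns named HCA and HCC. The 3 columns of WT at 12 months were identical and were counted as 1 library, so 2 columns were left out and 97 libraries in 32 groups were used. Groups came from genotype, age and tumour status in the labels. Left out were 1267 rows of small RNAs, which this kind of library does not measure, and 115 rows with doubtful zeros. The latter were genes listed at 0 in some library although their median was at least 20 FPKM or their lowest other value at least 100 FPKM, as for the albumin gene Alb, where a 0 is more readily a failed estimate than an absent transcript. An alternative kept them.

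The depth of each library is not stated. It was estimated from the smallest step between the values of low genes, with gene lengths of the GENCODE vM21 annotation in place of the authors' annotation, so the numbers are approximate. They ran from 3520000 to 18600000 reads with a median of 7550000, and 1 of 97 libraries gave no estimate. Whole reads could not be recovered for each gene, since 46.8% to 80.5% of the low values lay at 1 or 2 steps, and no count test was run.

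The design fixed beforehand assumed counts and named limma on log2 values as the test for normalized values, which was used here. Values were taken as log2(FPKM + 1), genes were kept with at least 1 FPKM in at least 3 libraries, and limma with a trend in the prior variance gave each contrast of group means, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fit of all non-tumour groups (26 groups, 76 libraries, 12574 genes) gave the genotype comparisons, each as the mean of the differences at 1, 2, 7 and 12 months and at single ages, the interaction of both deletions, and age trends as slopes per doubling of age. A fit of the tumour groups and their comparison groups (11 groups, 36 libraries, 12301 genes) gave the tumour comparisons. Standard errors are those of limma after its moderation of variances.

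Named genes followed a rule fixed before the data were examined. It took genes past the threshold with a mean of at least 10 FPKM in some group of the comparison and a change of the same sign at each age or in each pair of groups, the 5 with the largest rise and the 5 with the largest fall for main comparisons and 3 and 3 for the others, and up to 3 genes of each list with the lowest adjusted p. Symbols made of Gm and a number, or ending in Rik, were passed over, but not other symbols of clone type. The 28 gene lists, also fixed beforehand, were lipogenesis, lipid uptake and droplets, cholesterol synthesis, bile acid synthesis and transport, fatty acid oxidation, gluconeogenesis and FoxO targets, ERK response, pericentral and periportal hepatocyte genes, xenobiotic metabolism, NRF2 targets, ER stress and ATF4, acute phase, chemokines and cytokines, interferon response, macrophage, neutrophil, T and NK cell, B cell and plasma cell, stellate cell and fibrosis, endothelial cell, cholangiocyte and ductular genes, cell cycle, fetal and liver tumour markers, sex-biased liver genes, erythroid cell and blood, pancreatic acinar cell, and adipocyte. Of their symbols 8 had no row. Each list was tested against the other genes with camera in limma, with a preset correlation of 0.01 and again with a correlation estimated from the data, and adjusted over the lists of a comparison. Some genes stand on more than 1 list, and many markers of other cell types are also expressed at low levels by hepatocytes.

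Replicate numbers are shared between groups in the labels. For 32 pairs of groups the deviations of same-numbered libraries from their group means were correlated over genes. In 2 pairs every correlation was over 0.1, between liver and tumour of PKO at 12 months (0.14 to 0.15) and of DKO at 7 months (0.21 to 0.35), and the numbers were taken to pair those libraries. Alternatives tried were the median scaled to be equal in every library, no filter, a pseudocount of 0.1, the replicate number as a block, a covariate made from Xist and 4 genes of the Y chromosome, only the groups of each comparison in the fit, and each library left out in turn. Added after seeing the data were fits without 1 month, without 12 months, over 3, 4, 5 and 9 months only, with the 1-month libraries weighted by their own spread, with the doubtful zeros kept, and without the 2 libraries that express Xist.

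The limma step was tested on simulated values with known changes, drawn from a normal distribution with the same spread for a gene in every group. The 1-month libraries varied more than the others, so the unchanged genes called do not measure false calls at 1 month or in averages that include it. For the average of PKO against WT (12574 genes) it called 22 of 53 genes changed by 0.5 log2 units (41.5%), 67 of 77 changed by 1 (87.0%) and 70 of 70 changed by 2, with 8 unchanged genes called. For PKO against WT at 7 months, with 3 libraries a side, it called 3 of 71 (4.23%), 26 of 64 (40.6%) and 57 of 65 (87.7%), with 4 unchanged genes called. For the tumour average (12301 genes) it called 31 of 69 (44.9%), 64 of 71 (90.1%) and 59 of 60 (98.3%), with 11 unchanged genes called. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.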

Results

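Liver RNA was sequenced from C57BL/6 mice of 4 genotypes at ages from 1 to 16 months. WT were wild-type controls, SKO carried a hepatocyte-specific deletion of Shp2 (the phosphatase encoded by Ptpn11), PKO a hepatocyte-specific deletion of Pten (the lipid phosphatase that opposes phosphoinositide 3-kinase), and DKO both deletions. Of the 99 samples, 3 columns of WT at 12 months held identical values and were counted as 1 library, which left 97 libraries in 32 groups. Groups held 3 libraries each, except WT at 12 months with 1, and the PKO tumours at 16 months with 4 labelled HCA and 5 labelled HCC. All 4 genotypes were present at 1, 2, 7 and 12 months, and WT with PKO also at 3, 4, 5 and 9 months. Tumour groups were PKO at 12 months and DKO at 7 and 12 months, each beside liver samples of the same genotype and age, and a separate pair of WT and PKO groups at 7 months whose PKO samples are titled liver, carry the word tumour in their age and stand in columns named HCA. The columns also name the PKO tumours at 12 months HCA and the DKO tumours HCC, where the titles say tumour. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. They give no sequencing batch or date.

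The reads behind the FPKM values were approximately 3520000 to 18600000 per library, with a median of 7550000 over the 96 libraries that allowed an estimate. The 1-month libraries stood apart from the rest. In those 12 libraries 47.3% to 63.0% of all table rows were at 0, against 31.5% to 47.9% in the other 85, although their estimated depth was similar, at a median of 7290000 reads. Their median SD within a group was 0.36 to 0.55 log2 units, against 0.15 to 0.33 in the other groups, and counts of changed genes are therefore also given without 1 month or with those libraries weighted by their own spread, choices made after seeing the data. Fold changes are on the scale of log2(FPKM + 1), which understates the change of genes with low values.

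The deleted genes were examined first, since they check the labels. Ptpn11 averaged 41.3 FPKM in WT at 2 months (35.1 to 47.2 in its 3 libraries) and 9.61 FPKM in SKO (8.26 to 10.7). Averaged over 1, 2, 7 and 12 months, Ptpn11 fell by 1.41 ± 0.13 (SE) log2 units in SKO (12 libraries against 10 WT libraries, limma adjusted p = 2.5e-11). In DKO it changed by -1.29 ± 0.13 (adjusted p = 1.0e-11), and in PKO by -0.21 ± 0.13, which did not pass the test (adjusted p = 0.286). Pten averaged 17.3 FPKM in WT and 8.34 FPKM in PKO at 2 months. It fell by 0.85 ± 0.09 in PKO (adjusted p = 6.2e-10) and by 0.66 ± 0.09 in DKO (adjusted p = 8.4e-08), while in SKO the change was 0.05 ± 0.09 (adjusted p = 0.83). At 12 months, where WT had 1 library, the changes of Pten in PKO (-0.75, adjusted p = 0.0933) and DKO (-0.70, adjusted p = 0.112) and of Ptpn11 in SKO (-1.29, adjusted p = 0.300) did not pass the test, and neither did Ptpn11 in DKO at 7 months (-0.73, adjusted p = 0.0520). Pten was lower in every PKO and DKO library than in every WT library of the same age and set, and Ptpn11 in every SKO and DKO library, so no library went against its genotype label. Whole liver also holds cells without the deletion, and whether the values cover the deleted exons is not given in the sources used here.

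**Figure D1:**
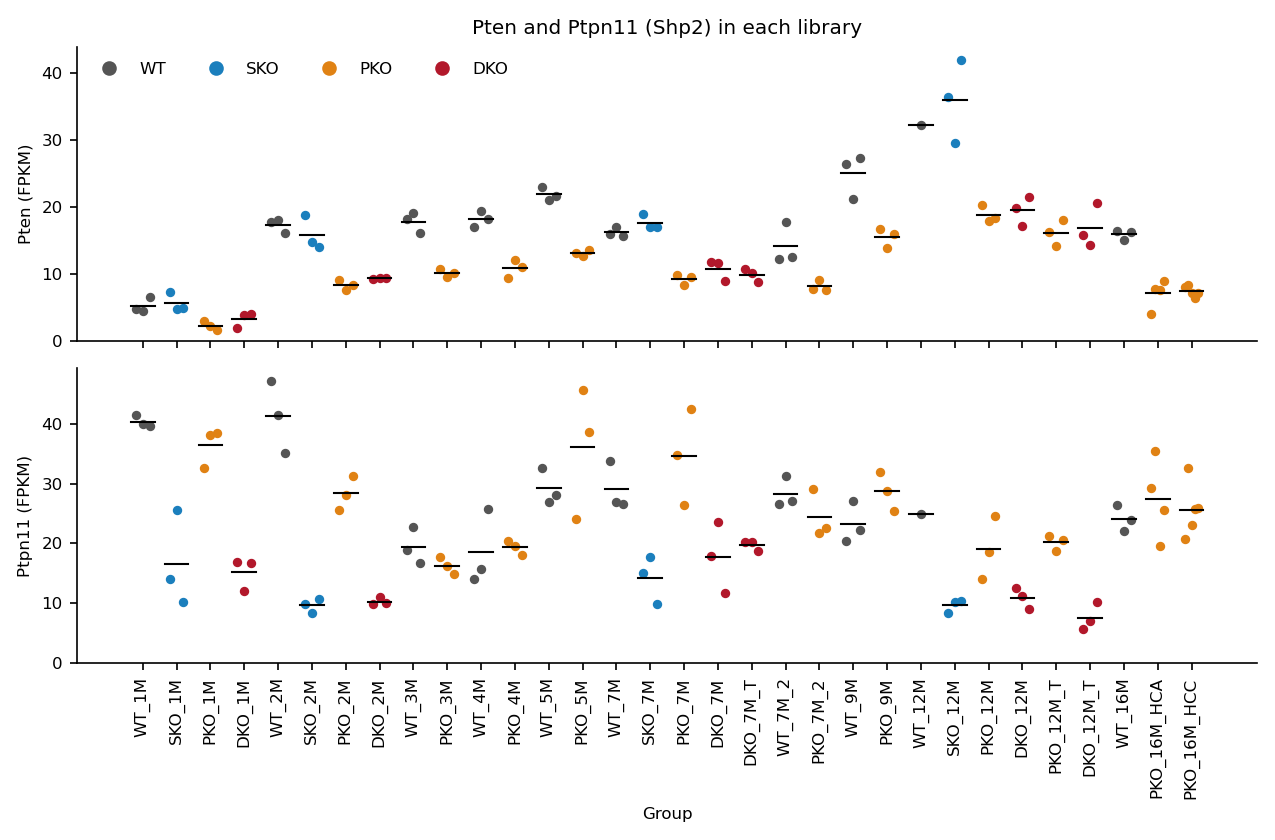
FPKM of Pten and Ptpn11 in each of the 97 libraries (points) with the group mean (line), by genotype and age. Pten lay at 7.60 to 9.07 FPKM in the PKO libraries at 2 months and at 16.1 to 18.1 FPKM in WT, and Ptpn11 at 8.26 to 10.7 FPKM in SKO and at 35.1 to 47.2 FPKM in WT.

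The comparison of SKO with WT asked which liver transcripts follow the loss of Shp2 in hepatocytes. By the list test with its preset correlation alone, genes of cholesterol synthesis, antioxidant NRF2 targets and macrophage markers were higher, while of 11 male-biased liver genes 4 were lower and 1, Cyp4a12b, higher. The largest rise among abundant genes was in Ly6d, which encodes a surface protein anchored by a lipid, from 9.33 FPKM in WT to 486 FPKM (log2 fold change 4.15 ± 0.39, 12 libraries against 10). These averages include 318 to 3622 FPKM in SKO and 8.03 to 62.3 FPKM in WT at 1 month, while at 2 months Ly6d was at 29.3 to 32.1 FPKM in SKO and 2.01 to 3.57 FPKM in WT, and without 1 month the change was 3.61. Ptgds, a prostaglandin D2 synthase, rose by 3.18 ± 0.48, Csad, an enzyme of taurine synthesis, by 2.55 ± 0.31, and Tmem98 by 2.35 ± 0.23. Lyz1 rose by 2.11 ± 0.30, although reads of this lysozyme gene can be shared with its near-identical neighbour. The largest falls were in Hsd3b5, a steroid dehydrogenase more abundant in male liver (-3.38 ± 0.51), Serpina1e (-2.88 ± 0.69), Mup3 (-2.71 ± 0.34), Enho, which encodes the secreted peptide adropin (-2.14 ± 0.35), and Sult5a1 (-2.13 ± 0.42). Serpina1e and Mup3 belong to families of near-identical copies, so their separate values are uncertain.

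Of the 19 measured genes of cholesterol synthesis, 11 rose, 0 fell and 8 did not pass the test in SKO, and 14 rose when p was adjusted over the list alone. Fdps rose by 1.12 ± 0.19, Cyp51 by 0.85 ± 0.15 and Fdft1 by 0.81 ± 0.14. The list stood above the other genes in the camera test with its preset correlation (adjusted p = 4.4e-11), but not with an estimated correlation (adjusted p = 0.0722), and without 1 month 10 of its genes rose. Among 14 NRF2 targets 6 rose and 0 fell, 9 adjusted over the list alone, with Gstm3 at 1.94 ± 0.25 and the quinone reductase Nqo1 at 1.02 ± 0.25 (camera adjusted p = 2.0e-06, and adjusted p = 0.0588 with an estimated correlation). Of 20 macrophage markers 8 rose, 15 adjusted over the list alone, led by the complement genes C1qb (1.36 ± 0.20) and C1qa (0.97 ± 0.19) and by Gpnmb (1.51 ± 0.28), with a camera adjusted p of 2.3e-11 and an adjusted p of 0.0588 with an estimated correlation. Of 20 stellate cell and fibrosis genes 4 rose, 9 adjusted over the list alone (camera adjusted p = 8.8e-06, adjusted p = 0.215 with an estimated correlation), and 1 did so without 1 month. Lipid uptake and droplet genes had 3 rises and 0 falls among 14, with Cd36, a fatty acid transporter, at 1.11 ± 0.18 (camera adjusted p = 0.00955, adjusted p = 0.0733 with an estimated correlation, 0.146 without 12 months). Fetal and tumour markers had 4 rises among 13 and 2 without 1 month. H19, an imprinted RNA of fetal liver, rose by 1.36 ± 0.39 (camera adjusted p = 1.7e-04, adjusted p = 0.0588 with an estimated correlation). Of the periportal genes 1 of 16 fell, Arg1 of the urea cycle at -0.82 ± 0.13. Of 20 sex-biased genes 1 rose and 4 fell. Of the 13 genes of the ERK response, the pathway that Shp2 feeds, 0 rose and 2 fell in limma, and 0 fell without 1 month. The list did not stand apart (camera adjusted p = 0.662).

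In SKO 867 genes passed the test, 535 higher and 332 lower, and without 1 month 635. Without 12 months 1320 passed, with the 1-month libraries weighted 429, and 268 with only the groups of the comparison in the fit. By age, 2100 genes passed at 1 month, 166 at 2 months, 71 at 7 months and 1 at 12 months. The 2100 became 14 with the 1-month libraries weighted and 0 with these groups fitted alone (759 at an unadjusted limma p under 0.05), and another split of the same 6 libraries gave 2649. At 12 months, where WT was 1 library assumed to vary like the other groups, the gene was Capn8, a calpain protease, named after its values were seen (-2.85 ± 0.36, adjusted p = 1.8e-06), and 305 genes had an unadjusted limma p under 0.05. With these groups fitted alone 0 passed in limma, with 505 unadjusted. The age counts moved when single libraries were left out, at 7 months from 71 to between 26 (without WT library 1) and 169 (without SKO library 0), and differences between ages were tested only as the trends given below.

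The comparison of PKO with WT asked which transcripts follow the loss of Pten. Genes of lipid droplets were higher by the list test with both correlations. By its preset correlation alone lipogenesis genes and markers of macrophages, stellate cells and bile ducts were higher, and genes of xenobiotic metabolism, bile acid synthesis and periportal hepatocytes were lower. Of 11 male-biased genes 4 were lower and 1 was higher. Cidea, which fuses lipid droplets, was at 0.180 FPKM in WT and 92.1 FPKM in PKO (log2 fold change 4.89 ± 0.22, 12 libraries against 10, limma adjusted p = 1.5e-25). Ly6d rose by 5.25 ± 0.39, Apoa4, an apolipoprotein of triglyceride-rich particles, by 4.53 ± 0.26 (108 to 2850 FPKM), the trefoil peptide Tff2 by 2.86 ± 0.46, galectin Lgals1 by 2.81 ± 0.20 and Anxa2 by 2.78 ± 0.21. Falls were largest in Cyp2c37 (-2.43 ± 0.38, of a family of close copies), Enho (-2.38 ± 0.35), Ang, which encodes the ribonuclease angiogenin (-2.27 ± 0.22), BC089597 (-2.21 ± 0.34) and Susd4 (-2.17 ± 0.26).

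In PKO 9 of 14 lipid uptake and droplet genes rose and 0 fell, 11 adjusted over the list alone, and this call held with an estimated correlation (camera adjusted p = 6.0e-17 preset and 7.8e-08 estimated). Mogat1, a monoacylglycerol acyltransferase, rose by 2.36 ± 0.22 and Plin2, a droplet coat protein, by 1.83 ± 0.19. Of 18 lipogenesis genes 11 rose, 11 adjusted over the list alone and 8 without 1 month, with Me1 at 1.34 ± 0.26, Elovl5 at 1.25 ± 0.20 and pyruvate kinase Pklr at 1.13 ± 0.21 (camera adjusted p = 4.1e-07, adjusted p = 0.120 with an estimated correlation). Cholesterol synthesis went the other way, with 7 of 19 lower, 7 adjusted over the list alone and 0 higher, such as Idi1 (-0.93 ± 0.25), Msmo1 (-0.90 ± 0.23) and Cyp51 (-0.68 ± 0.15), at a camera adjusted p of 0.00159 and an adjusted p of 0.302 with an estimated correlation. Bile acid genes fell in 7 of 19, among them the hydroxylases Cyp7b1 (-1.78 ± 0.32) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.13 ± 0.28), at a camera adjusted p of 0.00189 and an adjusted p of 0.151 with an estimated correlation. Of 12 genes of gluconeogenesis and FoxO targets 1 rose and 2 fell. The glucokinase gene Gck rose by 1.22 ± 0.24 and Pck1, the first enzyme of gluconeogenesis, fell by 0.94 ± 0.20 (camera adjusted p = 0.0555). The list passed with no filter (adjusted p = 0.0188), with a pseudocount of 0.1 (0.0290), without 12 months (0.0375) and without 1 month (0.00784), where 4 of its genes fell. Fatty acid oxidation genes rose in 4 of 18 and fell in 1 (camera adjusted p = 0.0555), with Fgf21, a fasting hormone, at 1.75 ± 0.34. That list passed with no filter (adjusted p = 0.0323), with the replicate number as a block (0.0282) and with only the groups of the comparison (0.0218). It also passed without 1 month (0.0158), where 7 rose and 0 fell.

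In PKO 7 of 16 periportal genes fell and 1 rose, with Cps1, the first enzyme of the urea cycle, at -1.58 ± 0.19 (camera adjusted p = 4.9e-04), and of 16 pericentral genes 0 rose and 4 fell, with the glutamate transporter gene Slc1a2 at -1.12 ± 0.23 (camera adjusted p = 0.00244). These calls were lost with an estimated correlation (adjusted p = 0.120 and adjusted p = 0.206). Xenobiotic metabolism fell in 6 of 13 genes (camera adjusted p = 5.4e-05), ER stress and ATF4 genes in 5 of 16 (camera adjusted p = 0.00480) and acute phase genes in 5 of 17 (camera adjusted p = 0.00685), such as the fibrinogen gene Fgg at -1.15 ± 0.19. Each of these lists was also lost with an estimated correlation (adjusted p = 0.120, 0.155 and 0.400), and the acute phase list without 1 month (adjusted p = 0.122). NRF2 targets rose in 7 of 14, with Gstm3 at 2.21 ± 0.25 and Cbr3 at 2.02 ± 0.24 (camera adjusted p = 1.8e-04, adjusted p = 0.125 with an estimated correlation). Macrophage markers rose in 12 of 20, stellate cell and fibrosis genes in 10 of 20 and ductular genes in 10 of 17, with Spp1, which encodes osteopontin, at 2.25 ± 0.38 and Col1a2 at 1.42 ± 0.28. Their camera adjusted p values were 3.0e-07, 3.6e-06 and 1.9e-05, and with an estimated correlation adjusted p = 0.120, 0.151 and 0.120. Chemokine and cytokine genes rose in 5 of 16 and fell in 1, while 9 rose without 1 month. Interferon genes rose in 4 of 15 (chemokine and interferon camera adjusted p = 0.00467 and 0.0173, adjusted p = 0.206 and 0.291 with an estimated correlation, 0.278 and 0.357 without 12 months). Among 5 adipocyte markers Fabp4 (2.30 ± 0.36) and Cfd (2.25 ± 0.36) rose and Adrb3 fell (-0.55 ± 0.18), and the list did not pass (camera adjusted p = 0.0954). It did without 12 months (adjusted p = 0.0366) and with the doubtful zeros kept (0.00112). Neutrophil (0 of 7 past the test), T and NK cell (0 of 8), endothelial (3 of 14 higher) and erythroid lists (1 of 7 lower) did not pass either, with camera adjusted p values of 0.871, 0.486, 0.0954 and 0.216. The endothelial list passed with only the groups of the comparison (adjusted p = 0.0414), the erythroid list with no filter (0.0320) and without 1 month (0.0330).

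In PKO 1843 genes passed, 1090 higher and 753 lower, and 2379 without 1 month. By age the counts were 2975 at 1 month, 132 at 2, 262 at 3, 190 at 4, 1025 at 5, 418 at 7, 495 at 9 and 201 at 12 months, the last against 1 WT library. At 1 month 171 passed with these libraries weighted and 13 with the groups fitted alone, and another split of the same 6 libraries gave 1668. Leaving out 1 library lowered the count at 2 months to 48 (PKO library 1), at 3 months to 101 (WT library 0), at 4 months to 53 (PKO library 2), at 5 months to 393 (PKO library 1), at 7 months to 167 (PKO library 0) and at 9 months to 235 (PKO library 1). Cidea was past the test at each age from 2 to 12 months, with log2 fold changes of 6.04 ± 0.39 at 2 months, 7.80 ± 0.39 at 3 months and 6.61 ± 0.55 at 12 months, 3 libraries in PKO each time. At 1 month it was listed at 0 in every WT and PKO library. When the 1-month libraries were left out of the fit, whose spread then became smaller, the counts at the other ages were higher, 396 at 2 months and 1990 at 5 months.

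The comparison of DKO with WT asked what follows the loss of both phosphatases. Averaged over the 4 ages, DKO had the most changed genes of the 3 genotypes. At 1 month PKO had more (2975 against 2753, weighted 171 against 62), but not with these groups fitted alone (13 against 159). Droplet genes and macrophage markers were higher by the list test with both correlations. Stellate cell, ductular and cell cycle genes were higher by its preset correlation alone, and 6 of 11 male-biased genes fell. Ly6d rose from 9.33 to 2157 FPKM (7.12 ± 0.39, 12 libraries against 10, limma adjusted p = 2.4e-21, with 4740 to 10414 FPKM at 1 month and 826 to 1525 FPKM at 2 months), Apoa4 by 5.43 ± 0.26, Cidea by 4.64 ± 0.22, the syntenin gene Sdcbp2 by 4.50 ± 0.28 and Gpnmb, a glycoprotein of lipid-laden macrophages, by 4.49 ± 0.28. Serpina1e was lower by -7.13 ± 0.69 and Mup3 by -4.64 ± 0.34, with the same doubt over near-identical copies. Hsd3b5 was lower by -5.33 ± 0.51 (70.7 FPKM in WT against 0.0925), the anion transporter Slco1a1 by -4.15 ± 0.44 and the sulfotransferase Sult2a8 by -3.58 ± 0.36.

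In DKO 16 of 20 macrophage markers rose and 0 fell, 17 adjusted over the list alone and 16 without 1 month (camera adjusted p = 8.4e-11 preset and 0.0458 with an estimated correlation). C1qb rose by 1.95 ± 0.20 and C1qa by 1.61 ± 0.19. Of 20 stellate cell and fibrosis genes 16 rose, 18 adjusted over the list alone, with the collagen gene Col4a1 at 1.57 ± 0.20 and the matrix protein gene Sparc at 1.36 ± 0.18 (camera adjusted p = 4.1e-09, adjusted p = 0.0603 with an estimated correlation). Of 17 ductular genes 11 rose, with Spp1 at 3.46 ± 0.38, Mmp7 at 2.67 ± 0.33 and Anxa5 at 2.63 ± 0.24 (camera adjusted p = 6.0e-06, adjusted p = 0.0609 with an estimated correlation). Cell cycle genes rose in 12 of 19 and in 15 without 1 month, among them the helicase gene Mcm2 (0.90 ± 0.13) and the proliferation marker Mki67 (1.06 ± 0.18), at a camera adjusted p of 8.0e-04 and an adjusted p of 0.145 with an estimated correlation. Fetal and tumour markers rose in 9 of 13 and fell in 1 (camera adjusted p = 1.9e-04 preset and 0.0484 estimated), with Cd44 at 1.41 ± 0.19. Droplet genes rose in 9 of 14 (camera adjusted p = 9.7e-12 preset and 6.2e-06 estimated), with Mogat1 at 3.58 ± 0.22 and Cd36 at 2.11 ± 0.18. Lipogenesis genes rose in 9 of 18 and fell in 2 (camera adjusted p = 0.00740, adjusted p = 0.355 with an estimated correlation, 0.0937 without 1 month), the fall including Mlxipl, a glucose-responsive transcription factor (-0.89 ± 0.13). Cholesterol genes rose in 5 of 19 (camera adjusted p = 0.0288, adjusted p = 0.544 with an estimated correlation, 0.0937 without 1 month and 0.0604 with those libraries weighted). NRF2 targets rose in 9 of 14 and fell in 1, led by Gstm3 (3.17 ± 0.25), at a camera adjusted p of 1.5e-04 and an adjusted p of 0.0951 with an estimated correlation. Chemokine genes rose in 5 of 16 and fell in 1, with Cxcl14 at 2.17 ± 0.27 (camera adjusted p = 0.0104, adjusted p = 0.236 with an estimated correlation, 0.0986 without 12 months).

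Periportal genes fell in 9 of 16 and rose in 2 in DKO, and this call held with an estimated correlation (camera adjusted p = 1.0e-05 preset and 0.0484 estimated). Hal, which degrades histidine, was lower by -2.47 ± 0.25 and the serine dehydratase Sds by -1.77 ± 0.26. ER stress and ATF4 genes fell in 8 of 16 (camera adjusted p = 8.0e-05 preset and 0.0490 estimated), with the chaperone Hsp90b1 at -0.89 ± 0.16. Bile acid genes fell in 7 of 19 and rose in 2 (camera adjusted p = 5.9e-04, adjusted p = 0.0967 with an estimated correlation), xenobiotic genes fell in 6 of 13 and rose in 1 (adjusted p = 5.9e-04 and adjusted p = 0.140), and pericentral genes fell in 4 of 16 and rose in 3, or in 1 without 1 month (adjusted p = 0.0188 and adjusted p = 0.355). For acute phase genes the summary measures differed in sign. Of 17 genes 3 rose, such as Orm2 (3.39 ± 0.50, one of several close copies), and 6 fell, such as Fgb (-1.29 ± 0.18), with a median of 0.13 and a mean of 0.36 while camera gave a lower direction that did not pass (adjusted p = 0.213). Of 20 sex-biased genes 2 rose and 6 fell, with a median of 0.09 and a mean of -0.98 (camera lower, adjusted p = 0.0121, adjusted p = 0.0516 with an estimated correlation and 0.0564 with a pseudocount of 0.1). The 6 falls were all among the 11 male-biased genes. Without 1 month 6 rose and 9 fell. DKO library 0 at 7 months expressed Xist at 12.6 FPKM, while the labels give no sex. Erythroid genes fell in 3 of 7 (camera adjusted p = 0.0131, adjusted p = 0.0967 with an estimated correlation) and acinar genes of the pancreas in 2 of 3 (camera adjusted p = 0.0127 preset and 0.0484 estimated, 0.148 with no filter and 0.0503 without 1 month).

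In DKO 3566 genes passed, 2319 higher and 1247 lower, and 4043 without 1 month. Separate ages gave 2753 genes at 1 month, 1709 at 2, 567 at 7 and 250 at 12 months. At 1 month 62 passed with these libraries weighted and 159 with the groups fitted alone, and at 2 months 3989 with the groups fitted alone. Leaving out 1 library at 7 months gave 329 to 394, with 351 for the DKO library that expresses Xist. Against the 1 WT library at 12 months 0 passed in limma with these groups fitted alone (1288 unadjusted). The count there fell to 75 without DKO library 1 and rose to 386 without DKO library 2.

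The comparison of DKO with PKO asked what the loss of Shp2 adds where Pten is already deleted. Cholesterol synthesis and cell cycle genes were higher in DKO by the list test with its preset correlation alone, and 7 of 11 male-biased genes were lower. Sult2a1, a hydroxysteroid sulfotransferase, was at 0.284 FPKM in PKO and 85.8 FPKM in DKO (4.58 ± 0.40, 12 libraries against 12, limma adjusted p = 1.3e-12). Orm2 (2.67 ± 0.44), Sult2a2 (2.40 ± 0.38), Orm3 (2.21 ± 0.37) and the zinc transporter gene Slc39a5 (2.17 ± 0.21) followed. Lower in DKO were Serpina1e (-4.04 ± 0.62), Mup3 (-3.94 ± 0.30), the testosterone hydroxylase Cyp2d9 (-3.28 ± 0.31), Rgs16 (-2.92 ± 0.49) and Hsd3b5 (-2.79 ± 0.45). Of 19 cholesterol genes 14 were higher and 0 lower, 16 adjusted over the list alone and 11 without 1 month, with Cyp51 at 0.88 ± 0.13 and Dhcr24 at 0.79 ± 0.10 (camera adjusted p = 5.8e-14, adjusted p = 0.0603 with an estimated correlation). Of 19 cell cycle genes 11 were higher and 6 without 1 month, with Cdkn3 at 1.56 ± 0.29 and Cdc20 at 1.11 ± 0.19 (camera adjusted p = 1.9e-07, adjusted p = 0.0603 with an estimated correlation). Sex-biased genes were lower in 7 of 20 and higher in 2, and this call held (camera adjusted p = 0.00206 preset and 0.0436 estimated). Macrophage markers were higher in 6 of 20, 12 adjusted over the list alone, but in 2 without 1 month (camera adjusted p = 1.0e-06, adjusted p = 0.117 with an estimated correlation), and stellate cell genes in 4 of 20 and in 0 without 1 month (camera adjusted p = 8.3e-05, adjusted p = 0.229 with an estimated correlation). In bile acid genes 2 were higher and 6 lower, with Cyp7a1 higher by 1.94 ± 0.25 and its repressor Nr0b2 lower by -1.54 ± 0.28. Their median was 0.01 and their mean -0.19, with camera lower (adjusted p = 0.0354, adjusted p = 0.356 with an estimated correlation, 0.0613 with the 1-month libraries weighted and 0.0623 without 12 months). Median and mean were also above 0 while camera gave a lower direction, without passing, for fatty acid oxidation (0.07 and 0.06, adjusted p = 0.460) and pericentral genes (0.02 and 0.06, adjusted p = 0.934). In all 1149 genes passed, 779 higher and 370 lower, and 662 without 1 month or 554 with those libraries weighted. With the median scaled the share higher was 78.1% against 67.8%.

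Whether the effects of both deletions add up was tested as an interaction, DKO minus SKO minus PKO plus WT. It passed for 47 genes, 19 above and 28 below additivity, and for 32 without 1 month. With the 1-month libraries weighted 5 passed, of those named here Sult2a1 and Atp1b1, and afterwards named Atg3, Atp6v1e1 and Ptges2. With only these groups fitted 23 passed, and without 12 months 155. Sult2a1 lay above additivity by 4.30 ± 0.60 log2 units (22 libraries of DKO and WT against 24 of SKO and PKO, limma adjusted p = 2.3e-05), Atp1b1, a subunit of the sodium pump, by 1.29 ± 0.28, Strn3 by 0.96 ± 0.22, Dnajc22 by 0.90 ± 0.21 and the phosphatase gene Dusp16 by 0.80 ± 0.18. Below it were Mup1 (-4.72 ± 0.78), Cyp4a12b (-2.18 ± 0.54), Cyp2d9 (-2.05 ± 0.47), the carboxylesterase gene Ces3b (-1.70 ± 0.37) and Mup11 (-1.63 ± 0.40), of which the Mup and Cyp4a12 genes have near-identical copies. Alas2, the heme synthesis enzyme of red cells, was below by -1.08 ± 0.23. The cell cycle list lay above additivity with 0 of 19 genes past the limma test, 5 adjusted over the list alone (camera adjusted p = 0.00255, adjusted p = 0.550 with an estimated correlation), and its call was lost without 1 month (adjusted p = 0.248). Below lay the erythroid list (adjusted p = 0.00255, 0.128 estimated), NRF2 targets and B cell genes (0.0151 for each, 0.550 estimated), endothelial genes (0.0230, 0.380 estimated) and interferon genes (0.0485, 0.591 estimated). Without 1 month the erythroid and endothelial calls were lost (adjusted p = 0.0755 and 0.0762), and without 12 months those of NRF2 targets, B cell, endothelial and interferon genes (adjusted p = 0.511, 0.149, 0.647 and 0.740). The count moved to 200 without SKO library 0 at 1 month and to 72 without PKO library 1 at 1 month. With the median scaled 53.2% of the genes lay above additivity, against 40.4%.

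**Figure D2:**
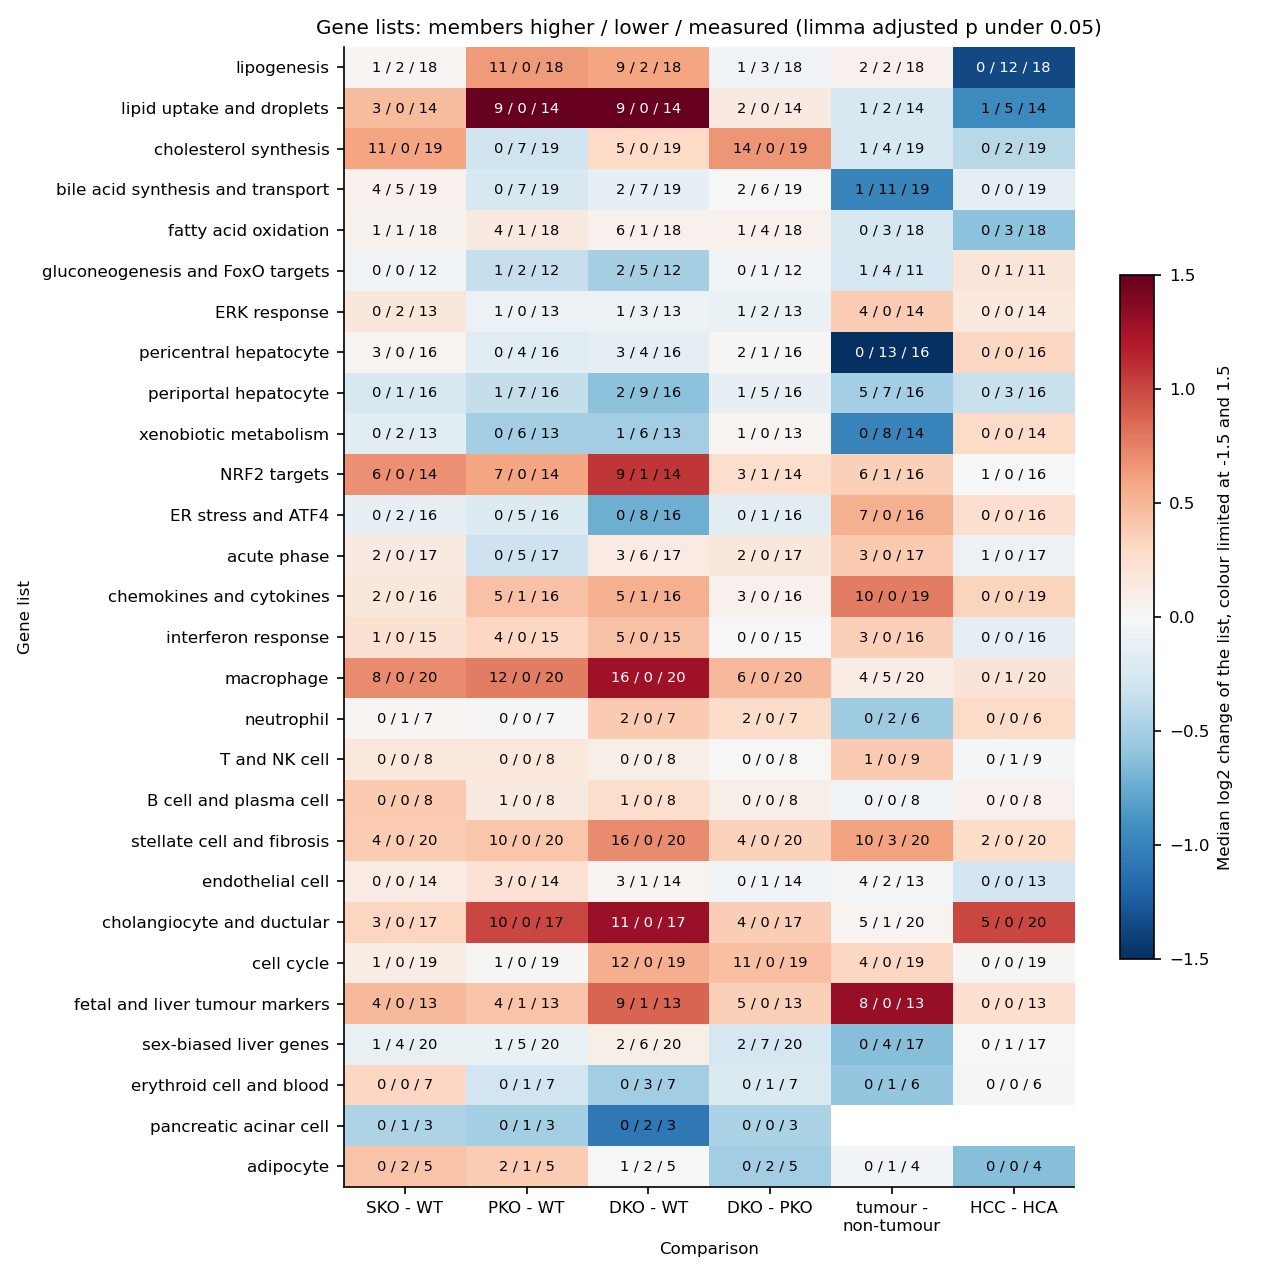
Median log2 fold change (colour, limited to -1.5 and 1.5) of 28 gene lists in 6 comparisons, and in each cell the genes past the limma test that were higher, those lower, and those measured. Droplet genes had 9 of 14 higher in both PKO and DKO against WT, and pericentral genes 13 of 16 lower in tumours.

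Age trends asked whether the difference from WT changed with age, as a slope per doubling of age. In PKO 1344 genes passed, 867 rising and 477 falling relative to WT, but 175 did so without 1 month, 275 with it weighted and 4 over 3, 4, 5 and 9 months alone. The trypsin inhibitor Spink1 rose by 1.76 ± 0.29 per doubling, S100a9, a calcium-binding protein of neutrophils, by 1.70 ± 0.34 and Cidea by 1.47 ± 0.14, while Hsd3b5 changed by -2.43 ± 0.32, Slco1a1 by -1.87 ± 0.28 and Serpina1e by -1.79 ± 0.44 (24 PKO and 22 WT libraries). Over 3, 4, 5 and 9 months the slope of Cidea was -0.39. The genes that passed over those 4 ages, named after their values were seen, were Mup10 (2.56 ± 0.50), Mup9 (-3.66 ± 0.68), Srgap3 (-0.87 ± 0.16) and 4930563F08Rik (-0.78 ± 0.12). The trend in DKO passed for 153 genes, 12 without 1 month and 6 with it weighted, with Hamp2, a close copy of the hepcidin gene (1.88 ± 0.46), Cyp2c69 (1.61 ± 0.35) and Mmp7 (1.02 ± 0.24, listed at 0 in WT at 1 and 12 months) rising and Elovl3 (-1.55 ± 0.37), Mup20 (-1.41 ± 0.34) and Sult5a1 (-1.23 ± 0.31) falling. In SKO it passed for 38 genes, 3 without 1 month and 4 with it weighted (Adam11, Amn, Kptn and Micu1, named after their values were seen), with the cyclin gene Ccnd1 (0.71 ± 0.17), the interferon-inducible GTPase gene Iigp1 (0.70 ± 0.11) and Slc39a14 (0.61 ± 0.14) rising and Mgst2 (-1.04 ± 0.25), Tmem98 (-0.93 ± 0.17) and Amn (-0.93 ± 0.14) falling. Those of SKO without 1 month were C1s2 (-2.32 ± 0.40), Mup10 (-1.78 ± 0.28) and Pebp1 (-0.86 ± 0.17), also named afterwards. Of 100 splits of the same libraries, the real one included, 52 gave as many genes for SKO and 13 for DKO.

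**Figure D3:**
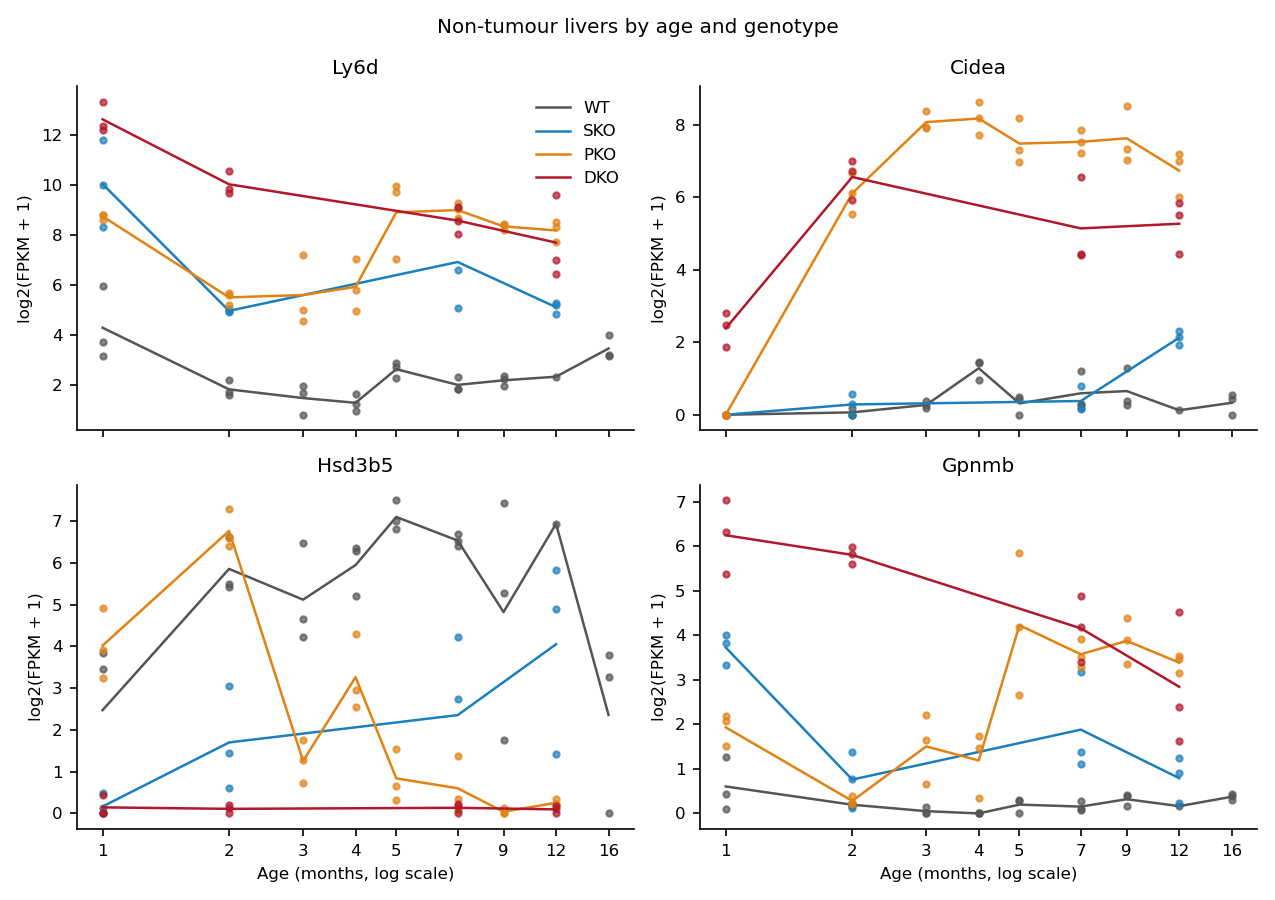
Levels of Ly6d, Cidea, Hsd3b5 and Gpnmb as log2(FPKM + 1) against age in months on a log axis, in WT, SKO, PKO and DKO, with a point for each library and lines through group means. Hsd3b5 in WT averaged 61.6 FPKM at 2 months and 92.1 FPKM at 7 months, and in DKO 0.0808 and 0.101 FPKM.

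Among the WT libraries alone 4712 genes had a slope with age from 1 to 16 months, 3063 upward and 1649 downward, and 2395 without 1 month, where 987 went up and 1408 down. Of 13 fetal and tumour markers 5 fell and 0 rose, although the list did not pass (camera adjusted p = 0.0638). It did with the median scaled (adjusted p = 0.0222) and with the 1-month libraries weighted (0.0416). Igf2bp3, which binds the mRNA of a fetal growth factor, fell by 0.71 ± 0.07 per doubling of age (limma adjusted p = 4.2e-13), Lin28b by 0.30 ± 0.04 and the cyclin gene Ccnb1 by 0.56 ± 0.09. Cell cycle genes fell in 11 of 19 (camera adjusted p = 1.7e-04) and interferon genes in 9 of 15, with Usp18 at -0.75 ± 0.10 (camera adjusted p = 5.4e-04), and both lists were lost with an estimated correlation (adjusted p = 0.527 for each) and over 3, 4, 5 and 9 months (0.860 and 0.349), and the cell cycle list also without 1 month (0.945). Ugt1a1, which conjugates bilirubin, rose by 1.05 ± 0.14, Mxd3 by 0.93 ± 0.06, Cyp4a12a by 0.95 ± 0.14, Mup21 by 0.95 ± 0.18 and Mup20 by 0.94 ± 0.18. Falls were seen for Rps27 (-1.29 ± 0.48), Tff3 (-1.20 ± 0.30), Igfbp1 (-1.14 ± 0.19), Rpl34 (-1.02 ± 0.15) and Sult2a1 (-0.96 ± 0.17). Without 1 month the slopes of Mup21 (-0.25), Mup20 (-0.23), Cyp4a12a (-0.14) and Sult2a1 (0.012) had the opposite sign, so these rest on the youngest libraries. Over 3, 4, 5 and 9 months those of Rps27 (0.67), Tff3 (0.29), Mup21 (-0.062), Mup20 (-0.72) and Sult2a1 (0.20) did. Pten rose in WT by 0.37 ± 0.04 per doubling. With the median scaled 76.0% of the slopes were upward, against 65.0%. Age and the time of collection cannot be told apart here.

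The tumour comparison asked how tumours differ from liver of the same genotype and age, averaged over PKO at 12 months and DKO at 7 and 12 months. Pericentral, bile acid and xenobiotic genes were lower in tumours, and fetal and tumour markers were higher. Cyp8b1, the sterol hydroxylase that sets the type of bile acid, was at 276 FPKM in liver and 16.0 FPKM in tumours (-5.12 ± 0.68, 9 libraries against 9, limma adjusted p = 5.6e-06). Cyp2c50 (-4.08 ± 0.53), Cyp4a14 (-3.79 ± 0.41), Cyp2e1 (-3.64 ± 0.42) and Rgn (-3.56 ± 0.37) were also lower. Spink1 rose by 4.88 ± 0.67, Ugt1a2 by 4.47 ± 0.78, the trefoil peptide Tff3 by 3.90 ± 0.79, the prohormone-processing Cpe by 3.64 ± 0.58 and Mgst2 by 3.42 ± 0.56. Pten (-0.17) and Ptpn11 (-0.06) did not differ past the test.

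Of 16 pericentral genes 13 were lower in tumours and 0 higher, 13 adjusted over the list alone, with glutamine synthetase Glul at -2.17 ± 0.22, and the call held (camera adjusted p = 7.0e-17 preset and 0.0201 estimated). Bile acid genes were lower in 11 of 19 and higher in 1 (camera adjusted p = 2.0e-09 preset and 0.0201 estimated), among them Cyp7a1 (-3.37 ± 0.32) and the uptake transporter Slc10a1 (-3.49 ± 0.42). Xenobiotic genes were lower in 8 of 14, with Cyp3a11 at -3.17 ± 0.38 (camera adjusted p = 1.7e-09 preset and 0.0201 estimated). Fetal and tumour markers rose in 8 of 13 (camera adjusted p = 2.2e-06 preset and 0.0244 estimated), with the desaturase Scd2 at 2.32 ± 0.21, Golm1 at 1.95 ± 0.26 and the cell cycle inhibitor Cdkn1a at 1.75 ± 0.28. ER stress and ATF4 genes rose in 7 of 16, with the serine synthesis enzyme Psat1 at 1.94 ± 0.32, chemokines in 10 of 19, with Ccl9 at 1.32 ± 0.28, and ERK response genes in 4 of 14, with Ier3 at 2.20 ± 0.43. Their camera adjusted p values were 0.00253, 0.00262 and 0.0198, and adjusted p = 0.363, 0.363 and 0.443 with an estimated correlation. Acute phase genes rose in 3 of 17, with the iron-binding lipocalin Lcn2 at 440 FPKM in liver and 3477 FPKM in tumours (3.13 ± 0.42), at a camera adjusted p of 0.0176 and an adjusted p of 0.389 with an estimated correlation. Periportal genes had 5 higher and 7 lower of 16 (camera lower, adjusted p = 0.0300, adjusted p = 0.353 with an estimated correlation, 0.0828 with the replicate number as a block). Macrophage markers had 4 higher and 5 lower of 20, of which Cd9 rose by 1.46 ± 0.22 and the resident macrophage gene Cd5l fell by 1.88 ± 0.42. The macrophage median was 0.11 and its mean -0.11, and the list did not pass (camera adjusted p = 0.814). Stellate genes rose in 10 of 20 and fell in 3, Col4a1 at 1.67 ± 0.24 and Dcn at -1.21 ± 0.19 (camera adjusted p = 0.0463, adjusted p = 0.548 with an estimated correlation, 0.123 with only the groups of the comparison, 0.0726 with the block and 0.101 without the 2 libraries that express Xist). In all 2374 genes passed, 1431 higher and 943 lower.

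Single tumour groups had fewer calls. In PKO at 12 months 265 genes passed (3 libraries against 3), led by Mgst2 (6.27 ± 0.98), Spink1 (5.23 ± 1.16) and Anxa13 (4.15 ± 0.88), with Cyp8b1 (-4.29 ± 1.17), Slc10a1 (-4.28 ± 0.72) and Cyp3a11 (-3.61 ± 0.66) lower. DKO tumours at 12 months had 558 genes, with the progesterone-metabolising Akr1c18 (4.83 ± 1.14), Spink1 (4.53 ± 1.16) and alpha-fetoprotein Afp (3.66 ± 0.71) higher, and Cyp8b1 (-6.49 ± 1.17), Cyp2e1 (-6.11 ± 0.73) and Cyp4a14 (-5.48 ± 0.71) lower. DKO tumours at 7 months had 340 genes, with Spink1 (4.89 ± 1.16), Cpe (4.27 ± 1.01) and Gpx2 (4.16 ± 0.80) higher and Cyp8b1 (-4.57 ± 1.17), Cyp2c50 (-3.88 ± 0.92) and Cyp2c38 (-3.06 ± 0.61) lower. In this last group, where replicate numbers paired tumour and liver libraries, 201 genes passed with the pair as a block. Its library 0 and the liver library 0 expressed Xist (10.8 and 12.6 FPKM, at most 0.653 elsewhere), and without both libraries 0 genes passed in limma, with 1297 at an unadjusted p under 0.05. Leaving out liver library 0 alone also gave 0 in limma, with 1534 unadjusted, and leaving out tumour library 1 alone gave 4 (Arhgap22, Arhgap27, Gm6644 and Slc39a4, named after their values were seen). The count of PKO at 12 months fell to 27 without tumour library 1, and that of DKO at 12 months to 182 without liver library 0, and rose to 937 without liver library 1. With only the groups of each comparison in the fit 876 genes passed in PKO at 12 months, 809 in DKO at 7 months and 0 in limma in DKO at 12 months (1669 unadjusted).

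**Figure D4:**
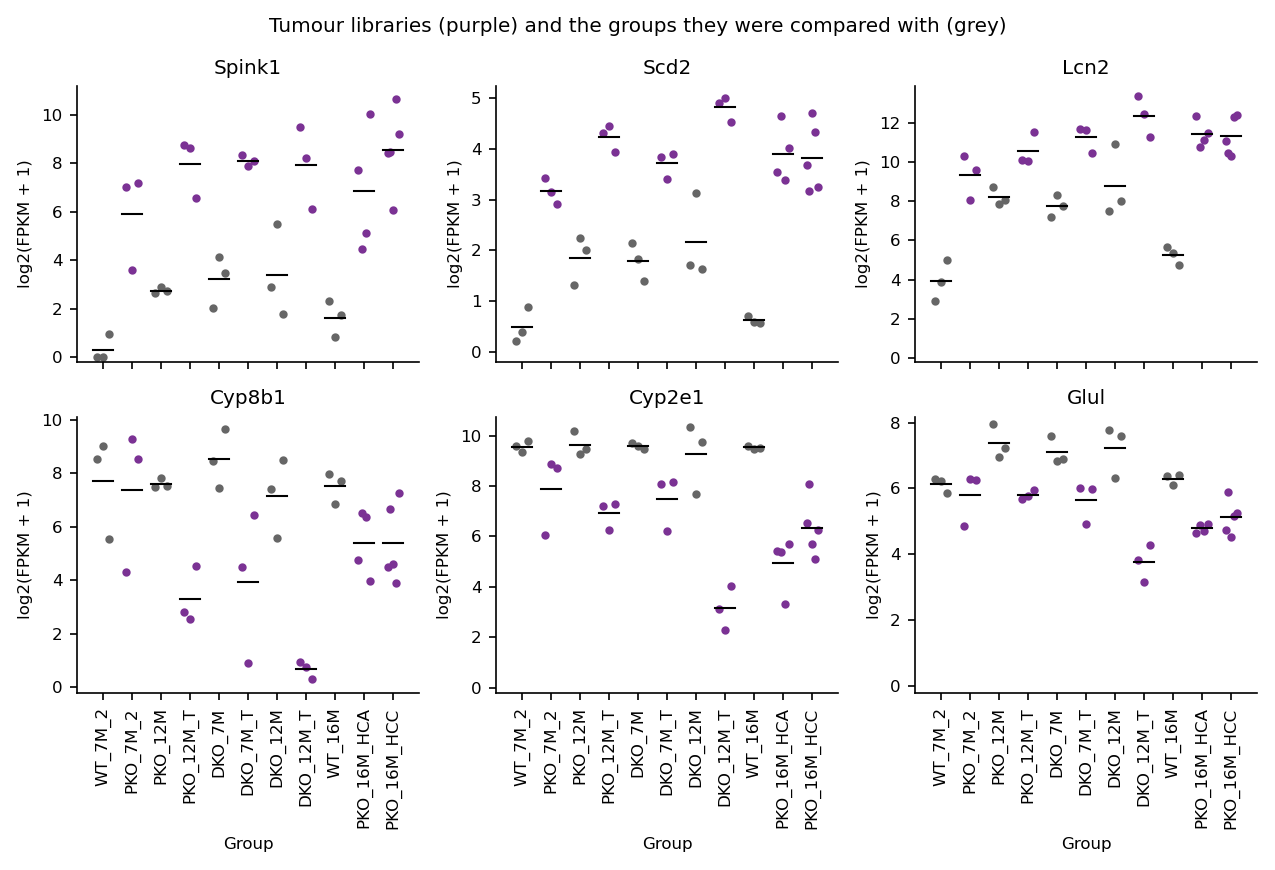
Levels of Spink1, Scd2, Lcn2, Cyp8b1, Cyp2e1 and Glul as log2(FPKM + 1) in tumour libraries (purple points) and in their comparison groups (grey points), with the group mean as a line. Averaged over 3 pairs of groups, Spink1 was at 315 FPKM in tumours and 11.2 FPKM in liver.

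The separate PKO set at 7 months, in columns named HCA, differed from its own WT set in 2264 genes, 1321 higher and 943 lower (3 libraries against 3). Ly6d (7.66 ± 0.62), Cidea (6.37 ± 0.86) and the ubiquitin-like gene Ubd (6.20 ± 1.02) were higher, and Hsd3b5 (-4.90 ± 0.46), Serpina1e (-4.40 ± 1.37) and Slco1a1 (-3.64 ± 0.74) lower. Leaving out PKO library 0 of this set gave 1084 genes, leaving out WT library 1 gave 1134, and fitting these groups alone gave 608. At 16 months the HCA samples differed from WT liver in 4678 genes and the HCC samples in 5566. In HCA Apoa4 (7.14 ± 0.67), Ly6d (6.79 ± 0.58) and the cornified envelope gene Sprr1a (6.34 ± 0.86) were higher, and Igfbp2 (-6.33 ± 1.07), Sult2a8 (-5.74 ± 0.62) and Cyp2c50 (-5.71 ± 0.86) lower. HCC samples had Sprr1a (7.71 ± 0.82), the guanylate cyclase ligand gene Guca2b (6.96 ± 1.40) and Spink1 (6.92 ± 1.04) higher, and Igfbp2 (-6.17 ± 1.02), Mup3 (-5.77 ± 1.1) and Sult2a8 (-5.70 ± 0.60) lower. Guca2b, Igfbp2 and Sprr1a in HCC, and Apoa4 in HCA, had a library far from the others in FPKM without log. Because these sets hold no PKO liver without tumour, their differences from WT hold both genotype and tumour.

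The comparison of HCC with HCA asked how both tumour labels differ within PKO at 16 months (5 libraries against 4). By the list test with its preset correlation alone lipogenesis genes were lower in HCC and ductular genes higher. Of 18 lipogenesis genes 12 were lower and 0 higher, 16 adjusted over the list alone, with Pklr at -1.78 ± 0.27 and the acetyl-CoA carboxylase Acaca at -1.46 ± 0.29 (camera adjusted p = 5.5e-16, adjusted p = 0.127 with an estimated correlation). Droplet genes were lower in 5 of 14, with Mogat1 at -2.17 ± 0.53 (camera adjusted p = 5.6e-05, adjusted p = 0.181 with an estimated correlation), and fatty acid oxidation genes in 3 of 18, with Cpt1a, which brings fatty acids into mitochondria, at -1.18 ± 0.22 (camera adjusted p = 2.5e-06, adjusted p = 0.374 with an estimated correlation). Ductular genes were higher in 5 of 20, with Cd24a at 1.87 ± 0.53 and Mmp7 at 3.41 ± 0.95, the latter at 791 FPKM in HCC library 0 and at most 215 FPKM in the other HCC libraries (camera adjusted p = 9.0e-04, adjusted p = 0.770 with an estimated correlation). The antimicrobial lectin Reg3g (4.56 ± 1.25), Ccl17 (3.71 ± 0.86), Ccl20 (3.64 ± 0.92) and the leukotriene synthase Ltc4s (3.10 ± 0.81) were higher. Apoa4 (-3.66 ± 0.59, limma adjusted p = 9.3e-04), Psapl1 (-2.54 ± 0.60), the intestinal fatty acid binding protein Fabp2 (-2.52 ± 0.33), Gpnmb (-2.46 ± 0.58) and Cyp17a1 (-2.41 ± 0.70) were lower. In all 665 genes passed, 339 higher and 326 lower, but 154 without HCA library 1, 1262 without HCA library 0 and 9 when these groups were fitted alone.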

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

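The fits and splits with the 1-month libraries weighted by their own spread were tests chosen after the result was seen. Libraries far from the others of their group were looked for in 72 values of named genes among the HCA and HCC samples, and 9 were found. The limit marks about 1 in 20 by chance where values follow a normal distribution. It was applied to FPKM without log, so the 9 cannot be set against that share. Each was marked by the gap between the extreme library and its nearest neighbour, as a share of the range of its group. Apoa4 in HCA had a gap of 0.870 of the range, with library 1 at 10381 FPKM and the others at 4683 to 5426. Guca2b in HCA had a gap of 0.841, with library 3 at 52.6 FPKM and the others at 2.73 to 10.7. For Sprr1a in HCC the gap was 0.765, with library 3 at 833 FPKM and the others at 138 to 302. For Igfbp2 in HCC it was 0.895, with library 1 at 27.3 FPKM and the others at 1.35 to 4.07. Cyp2c50 in HCC had 0.830, with library 1 at 208 FPKM and the others at 16.7 to 49.1. For Guca2b in HCC the gap was 0.874, with library 0 at 1065 FPKM and the others at 72.8 to 197. Mmp7 in HCC had 0.737, with library 0 at 791 FPKM and the others at 9.62 to 215. Hadha in HCC had 0.849, with library 2 at 94.6 FPKM and the others at 33.2 to 42.5. Cyp2f2 in HCC had 0.752, with library 2 at 401 FPKM and the others at 26.6 to 119.

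Differences between the effects of 1 deletion with and without the other were marked by the interaction test, which passed for 47 genes in limma. Above additivity lay Sult2a1 (4.30), Atp1b1 (1.29), Strn3 (0.96), Dnajc22 (0.90) and Dusp16 (0.80), and below it Mup1 (-4.72), Cyp4a12b (-2.18), Cyp2d9 (-2.05), Ces3b (-1.70) and Mup11 (-1.63). Of 100 splits of the same libraries within their ages 4 gave as many genes, the real one included, and the highest other split gave 102. These splits mixed all 4 genotypes, which also broke up the effect of each deletion, so they cannot test additivity alone. With the 1-month libraries weighted 5 genes passed, of those listed Sult2a1 and Atp1b1, and 14 of 100 splits gave as many (highest other 22), so chance was not excluded in that fit.

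Differences between ages in the effect of a deletion were marked by the test of the slope per doubling of age. It passed for 38 genes in SKO, with Ccnd1 (0.71), Iigp1 (0.70) and Slc39a14 (0.61) rising against WT and Mgst2 (-1.04), Tmem98 (-0.93) and Amn (-0.93) falling. As many genes were called in 52 of 100 splits, so chance was not excluded for SKO, and the highest other split called 404 (cause not traced). With the 1-month libraries weighted the SKO slope passed for 4 genes, a count reached in 53 of 100 splits, and the highest other called 97. In PKO the slope passed for 1344 genes, among them Spink1 (1.76), S100a9 (1.70) and Cidea (1.47) with rising and Hsd3b5 (-2.43), Slco1a1 (-1.87) and Serpina1e (-1.79) with falling differences. The real split was the only 1 of 100 to call as many, and the highest other called 430. These splits mixed PKO with WT at each age, so they cannot tell the slope from the average difference. In DKO it passed for 153 genes, with Hamp2 (1.88), Cyp2c69 (1.61) and Mmp7 (1.02) rising and Elovl3 (-1.55), Mup20 (-1.41) and Sult5a1 (-1.23) falling. As many were called in 13 of 100 splits, so chance was not excluded for DKO, and the highest other called 1142 (cause not traced). With the 1-month libraries weighted the DKO slope passed for 6 genes, as many as in 20 of 100 splits, and the highest other called 133.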

How the results depend on the processing

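The fits without 1 month, without 12 months, over 3, 4, 5 and 9 months, with the 1-month libraries weighted by their own spread, with the doubtful zeros kept and without the 2 libraries that express Xist were tests chosen after seeing the data. Under all alternatives run, the counts of the PKO and DKO averages against WT, of the tumour average and of HCA and HCC against WT stayed within 1.5 times those reported. For the other counts below the cause was not tested, except that fits with fewer libraries estimate the spread from fewer values. Among named genes, those that kept their direction and side of the threshold were 576 of 582 with the median scaled, 563 with no filter, 555 with a pseudocount of 0.1, 573 with the sex gene covariate, 467 with only the groups of the comparison and 582 with the doubtful zeros kept, and in these fits none turned. With the replicate block 545 kept both and 37 lost their call, with the 1-month libraries weighted 343 and 84, without 12 months 275 and 33, and without the 2 libraries that express Xist 237 and 13. Without 1 month 334 kept both, 65 lost their call and 4 turned, and over 3, 4, 5 and 9 months 8 kept both, 10 lost their call and 7 turned. Of 94 list calls made with the preset correlation 12 held with an estimated correlation, and 82 were lost. Of 67 such calls in the non-tumour fit, 55 held without 1 month, 54 without 12 months and 60 with the 1-month libraries weighted. The estimated depth limits genes of low FPKM, where 1 or 2 reads make up a value.

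With only the groups of the comparison in the fit, SKO passed for 268 genes on average, the interaction for 23, and the SKO trend for 10. At single ages SKO gave 0 at 1 month (759 at an unadjusted p under 0.05 in limma), 1 at 7 months (Psmc3ip, 2.86) and 0 at 12 months (505 unadjusted in limma). PKO gave 13, 659, 88, 73, 377, 725, 186 and 394 at 1, 2, 3, 4, 5, 7, 9 and 12 months. DKO gave 159 at 1 month, 3989 at 2 months and 0 at 12 months (1288 unadjusted in limma). Tumours gave 876 in PKO at 12 months, 809 in DKO at 7 months and 0 in DKO at 12 months (1669 unadjusted in limma), the separate PKO set at 7 months 608, and HCC against HCA 9. At 12 months WT was 1 library, which was assumed to vary like the other groups.

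With the 1-month libraries weighted the SKO average fell to 429 genes and DKO against PKO to 554, while the interaction had 5 (Atg3, Atp1b1, Atp6v1e1, Ptges2 and Sult2a1). The slopes had 4 in SKO (Adam11, Amn, Kptn and Micu1), 275 in PKO and 6 in DKO. SKO had 14, 629, 249 and 2 genes (Capn8 and Chd3) at 1, 2, 7 and 12 months, against 2100, 166, 71 and 1 (Capn8). PKO had 171, 463, 842, 665, 2038, 975, 1219 and 533 at its 8 ages, against 2975, 132, 262, 190, 1025, 418, 495 and 201, and DKO 62, 2928, 1385 and 699 at its 4, against 2753, 1709, 567 and 250. Without 1 month DKO against PKO had 662 genes, and the slopes had 3 in SKO (C1s2, Mup10 and Pebp1), 175 in PKO, 12 in DKO and 2395 in WT. SKO then had 542 genes at 2 months and 188 at 7. PKO had 396, 821, 650, 1990, 903, 1182 and 450 from 2 to 12 months, and DKO 2930, 1296 and 579 at 2, 7 and 12 months. Among WT slopes, Mup21 turned to -0.25, Cyp4a12a to -0.14, Mup20 to -0.23 and Sult2a1 to 0.012. Without 12 months the SKO average rose to 1320, the interaction to 155 and the SKO slope to 163. Over 3, 4, 5 and 9 months the PKO slope had 4 genes past the test (4930563F08Rik, Mup9, Mup10 and Srgap3), Cidea turned to -0.39, and the WT slope had 2250. In WT, Mup21 turned to -0.062, Mup20 to -0.72, Rps27 to 0.67, Tff3 to 0.29, Sult2a1 to 0.20 and Ptpn11 to 0.21. The genes in brackets were named after their values were seen.

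With the median scaled the SKO slope had 19 genes, 57.9% of them rising against 44.7%, the PKO slope had 79.6% rising against 64.5%, and SKO at 1 month 38.2% higher against 48.4%. No filter gave 65 for the SKO slope and 43 for SKO at 12 months, and the sex gene covariate 23 for the SKO slope. A pseudocount of 0.1 gave 0 for SKO at 12 months (264 unadjusted in limma) and 159 for DKO at 12 months. Keeping the doubtful zeros gave 2 for SKO at 12 months (Capn8 and Rn45s). Leaving out the 2 libraries that express Xist gave 351 for DKO at 7 months and 0 for its tumours (1297 unadjusted in limma).

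With the replicate number as a block, the tumours of DKO at 7 months, where the numbers pair the libraries, had 201 genes against 340. In the tumour average, which joins both paired sets with an unpaired one, the block lost the list calls of periportal genes (camera adjusted p = 0.0828 against 0.0300) and stellate genes (0.0726 against 0.0463) and the call of Klf1, and gained that of NRF2 targets (0.0388 against 0.0558). Among the paired results it changed no other call. In the other pairs of groups the samples shared only a number, with correlations of -0.19 to 0.25. In SKO and DKO at 7 months (0.10 to 0.18) and at 12 months (0.07 to 0.15) every library correlated best with its own number, a hint from the data and not from the design. There the block gave 563 for the SKO average, 23 for the interaction, 15 and 50 for the SKO and DKO slopes, 2 for SKO (Capn8 and Gm16063), 63 for PKO and 75 for DKO at 12 months, and 442 for HCC against HCA.

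Each library was left out in turn except WT at 12 months, which has 1, and the values of named genes kept direction and side of the threshold 9427 times, lost the call 402 times and gained it 2 times. The interaction ran from 36 (SKO library 1 at 2 months) to 200 (SKO library 0 at 1 month), with 72 for PKO library 1 at 1 month. The SKO slope ran from 19 (SKO library 0 at 12 months) to 396 (SKO library 0 at 1 month), with 102, 79 and 95 for WT libraries 0, 1 and 2 and 117 for SKO library 1 at 1 month, 22 for WT library 0 at 7 months and 20 for SKO library 1 at 12 months. The DKO slope ran from 106 (DKO library 1 at 12 months) to 309 (WT library 2 at 1 month), with 265 for WT library 0 at 1 month.

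SKO at 1 month ran from 1669 (SKO library 2) to 3237 (library 0). At 2 months it ran from 53 (SKO library 1) to 204 (SKO library 0), with 63 and 60 for WT libraries 0 and 1. At 7 months it ran from 26 (WT library 1) to 169 (SKO library 0), with 30 and 46 for WT libraries 0 and 2 and 33 and 27 for SKO libraries 1 and 2. PKO at 2 months ran from 48 (PKO library 1) to 70 (PKO library 2), with 53 for PKO library 0 and 52, 66 and 51 for WT libraries 0, 1 and 2. At 3 months it ran from 101 (WT library 0) to 206 (WT library 1), with 139, 159 and 117 for PKO libraries 0, 1 and 2. At 4 months the range was 53 (PKO library 2) to 142 (PKO library 1), with 89 and 121 for WT libraries 1 and 2 and 118 for PKO library 0. At 5 months the range was 393 (PKO library 1) to 1322 (PKO library 0), with 615 for WT library 2 and 628 for PKO library 2. At 7 months PKO ran from 167 (PKO library 0) to 327 (PKO library 2), with 266, 236 and 269 for WT libraries 0, 1 and 2 and 259 for PKO library 1. At 9 months PKO ran from 235 (PKO library 1) to 359 (WT library 2), with 308 for WT library 1. DKO at 7 months ran from 329 (WT library 1) to 394 (DKO library 2), with 338 and 352 for WT libraries 0 and 2 and 351 and 331 for DKO libraries 0 and 1, and at 12 months from 75 (DKO library 1) to 386 (DKO library 2).

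Tumours of PKO at 12 months ran from 27 (tumour library 1) to 145 (tumour library 2), with 91, 39 and 79 for liver libraries 0, 1 and 2 and 111 for tumour library 0. Those of DKO at 7 months ran from 0 (liver library 0, 1534 unadjusted in limma) to 286 (tumour library 2), with 221 and 86 for liver libraries 1 and 2 and 160 and 4 for tumour libraries 0 and 1. Those of DKO at 12 months ran from 182 (liver library 0) to 937 (liver library 1), with 186 for liver library 2 and 206 for tumour library 0. The separate PKO set ran from 1084 (PKO library 0) to 2116 (WT library 2), with 1134 for WT library 1. HCC against HCA ran from 154 (HCA library 1) to 1262 (HCA library 0), with 346 for HCA library 2 and 245 and 292 for HCC libraries 0 and 1.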

Other observations

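Families of genes that share a symbol stem were tested after seeing the data, 148 families with at least 10 members, and the members below were named after their values were seen. In DKO the annexins, which bind membranes with calcium, were higher in 8 of 10 (camera adjusted p = 1.9e-05 with the preset correlation, adjusted p = 0.0995 with an estimated correlation). Anxa2 rose by 3.51 ± 0.21 log2 units (DKO average over 4 ages, limma adjusted p = 2.2e-20), Anxa5 by 2.63 ± 0.24 and Anxa13 by 1.85 ± 0.28. They were higher in 5 of 10 in PKO (camera adjusted p = 0.000171, 0.300 estimated) and in 6 of 10 in SKO (6.5e-05, 0.141 estimated), which became 3 of 10 without 1 month. The WAP domain genes Wfdc were higher in 6 of 10 in DKO (camera adjusted p = 0.0205, 0.243 estimated), with the secreted Wfdc2 at 4.16 ± 0.30 and Wfdc18 at 4.01 ± 0.59. The thioesterases Acot, which release fatty acids from coenzyme A, were higher in 7 of 11 (camera adjusted p = 0.0012, 0.243 estimated), among them the mitochondrial Acot2 (1.61 ± 0.21), Acot9 (1.79 ± 0.23) and Acot13 (1.01 ± 0.10). Without 1 month 8 annexins, 6 Wfdc and 6 Acot genes were higher in DKO, and 1 Wfdc gene was lower.

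The carboxylesterases Ces, enzymes that cleave esters of lipids and drugs, were lower in DKO than in PKO in 7 of 12, and this call held with an estimated correlation (camera adjusted p = 1.7e-07 preset and 0.0468 estimated). Ces3b was lower by -1.97 ± 0.25 (limma adjusted p = 6.5e-08), Ces3a by -1.16 ± 0.18 and Ces2a by -0.84 ± 0.15, and 5 of 12 passed without 1 month. The major urinary protein genes Mup were lower in 8 of 15 in the same comparison (camera adjusted p = 3.4e-14, 0.0849 estimated), with 5 of 15 without 1 month. In PKO against WT 7 of 15 Mup genes were higher and 1 lower (camera adjusted p = 0.0200, 0.580 estimated), and 5 were higher and 3 lower without 1 month, while 7 of 13 Cyp2c genes were lower and 1 higher (camera adjusted p = 0.000171, 0.490 estimated), with a median of -1.16 that became -0.30 without 1 month. Mup and Cyp2c members are near-identical, so their reads cannot be assigned with certainty. The genes of the large ribosomal subunit Rpl were lower in 14 of 50 in DKO, with a median of -0.13 (camera adjusted p = 0.000184, 0.467 estimated), and in 7 of 50 with library medians scaled equal. The median of each of these families kept its sign under that scaling.

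The 3 patterns below were found and tested on the same data, and the tests of the female-biased genes, of the other cell types, of Xist and of Y-linked genes in liver without tumour were chosen after the result was seen.

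Male-biased liver genes were lower in DKO than in WT in 6 of 11. Against WT, SKO and PKO each had 4 of 11 lower and 1 higher, so the falls were not confined to DKO. Sex of the animals as the whole cause of the pattern in DKO was argued against, since without the 2 libraries that express Xist 6 were still called lower, with a median of -1.38 against -1.51. The other DKO and WT libraries of this comparison had Xist at 0.315 FPKM or less and Ddx3y at 4.30 FPKM or more. A general fall of abundant hepatocyte transcripts was argued against by the medians of the male-biased genes (-1.51) and of 60 other genes of 4 hepatocyte lists (-0.29, permutation p = 0.00533). The permutation took genes as independent, while genes of a list vary together, so that p carries no weight. A shift of the sex-biased programme as a whole stays open as a hypothesis, with 2 of 9 female-biased genes called higher (Cyp17a1 and A1bg) and 0 lower in limma, also 0 at an unadjusted p under 0.05. Growth hormone was not tested.

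Macrophage, stellate and ductular markers were higher in DKO than in WT in 43 of 57. A lower share of hepatocyte RNA as the whole cause raises the markers of every other cell type alike. It was argued against by 37 markers of endothelial, lymphoid and erythroid cells, of which 4 were higher and 4 lower. Their median was 0.12, and that of the 57 was 0.95 (permutation p = 0.00024). The permutation took genes as independent, while markers of a cell type vary together, so that p carries no weight. Neutrophil markers were left out of this comparison, and 4 of 7 were higher in DKO without 1 month. The wide spread of the 1-month libraries was argued against, since 48 of the 57 were higher without 1 month. More macrophages, stellate and ductular cells, or higher transcription in each cell, stay open and were not tested.

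Y-linked genes were low in single tumour libraries, here counting the separate PKO set at 7 months, where Eif2s3y in library 0 was 0.244 FPKM and the mean of 4 Y-linked genes lay -1.67 from the WT mean. A female animal or tissue was argued against, since the highest Xist in the other libraries was 6.02% of the lower of the 2 that express it. In 9 of 20 libraries the 4 genes lay under the lowest 2.5% of 10000 matched sets. The sets were drawn from genes all over the table and the libraries share comparison groups, so this count does not settle a general loss of genes of that level. In HCC library 0, among the 9, Eif2s3y was 5.37 FPKM, against 3.62 to 4.97 FPKM in WT at 16 months. Of these 9 libraries 7 were set against WT (of 12) and 2 against liver of the same genotype (of 8), and livers without tumour set against WT from 2 to 12 months lay under that limit in 0 of 21 PKO and 1 of 8 DKO libraries, so a difference of genotype at 16 months stays open. Loss of the Y chromosome in part of the cells stays open as a hypothesis, since in 0 of those 9 libraries did the X-linked partners lie under the same limit.

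Splits of the libraries were counted, the real one included, 100 within ages or sets for each average and 100 among ages for the WT slope. Only the real split called as many genes in SKO (867, highest other 250), PKO (1843, 502), DKO (3566, 1027), DKO against PKO (1149, 316) and the tumour average (2374, 464), so chance was excluded there. For the WT slope (4712, 4080) offsets between age sets stay open. Chance was also excluded for HCA against WT, 1 of 35 splits (4678, 3376), and HCC against WT, 1 of 56 (5566, 2352). It stays open for HCC against HCA, 4 of 100 (665, 1851, cause not traced). For 3 libraries against 3 the 10 splits are too few for a share under 0.05. There SKO had 2100 genes at 1 month (highest other 2649, as many in 3 splits), 166 at 2 months (1) and 71 at 7 months (2). PKO had 2975 at 1 month (1668), 132 at 2 (0), 262 at 3 (1), 190 at 4 (5), 1025 at 5 (21), 418 at 7 (1) and 495 at 9 (7). DKO had 2753 at 1 month (936), 1709 at 2 (0) and 567 at 7 (0). The tumours had 265 in PKO at 12 months (0), 340 in DKO at 7 months (1) and 558 in DKO at 12 months (260), and the separate PKO set had 2264 (7). For the paired tumours of PKO at 12 and DKO at 7 months, the other 3 splits that part every pair gave 0, and those that keep a pair gave at most 1.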
